A study of Arabidopsis thaliana with 12 samples.

How the data were processed

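Total RNA of wild-type Arabidopsis thaliana plants of the Landsberg ecotype was measured on arrays, with 1 channel a sample, per the labels. All 12 samples came from plants treated with bromoxynil, a nitrile herbicide that blocks electron transport at photosystem II. Samples of the dark group (n = 6) were taken after 12 h in darkness, and samples of the light group (n = 6) 30 min after light was given back. The bromoxynil concentration was 500 µM in both groups. Groups and sample numbers 1 to 6 were taken from the sample titles. The labels do not say whether the samples came from separate plants or cultures, so p-values measure only the spread between these samples, which may be technical. Plants without bromoxynil were not analysed here.

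The deposited values are relative spot intensities on a linear scale. The values themselves show this: none is below 0, and the brightest spot has the value 100 on 10 of the 12 samples. Scanner, background correction and scaling by the authors are not given in the sources used here. The highest median intensity of a sample was 6.98 times the lowest, because light 1 and light 2 had medians of 3.88 and 3.90 and the other 10 samples lay between 0.559 and 0.654. By a rule set before the data were examined, a ratio above 1.25 called for quantile normalisation. Values of 0 were first set to the lowest positive value of the same sample, log2 was taken, and the 12 samples were quantile normalised. Of 3439 probes, 58 were listed at 0 in every sample and were left out, a step added after the data were seen. The other 3381 were tested, of which 188 were listed at 0 in 1 to 11 samples. The number of samples limits the precision, and the signal over background is unknown.

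The platform annotation gives 1 gene for 692 probes, several for 870 and none for 1877. Of the 692 genes, 690 were matched in the RefSeq gene table of assembly TAIR10.1, which was used for current names only. No gene was named from a probe with several genes. The array's genome build is not given in the sources used here, so no coordinates are printed.

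Light was compared with dark by limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05 over all tested probes, no covariate). Errors of log2 changes are standard errors, and intervals are 95% confidence intervals of limma. A total of 25 gene lists with 408 loci were fixed before the data were examined. A list with at least 5 measured members was tested with camera at a preset inter-gene correlation of 0.01, with the estimated correlation and with fry. The rule for named genes took the 10 largest rises and the 10 largest falls among called probes that moved the same way in all 6 sample numbers, and from each list its member with the largest change. It also took ELIP1, ELIP2, SIG5, LHCB1.3, RBCS1A, PSBS and NIT4. At most 2 probes without a gene name were to be printed in each direction.

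Questions about the sample numbers were examined in the data. Deviations from the group means were correlated between light and dark samples of the same number, across probes, which are not independent replicates. All 6 correlations lay between 0.337 and 0.492. Each dark sample correlated best with the light sample of its own number, so the numbers pair the samples across the groups. The main fit, as fixed before the data were examined, left this pairing out, as did the random block below. The sample number as a block was run as an alternative. The second check asked whether 1 and 2, 3 and 4, and 5 and 6 are repeat measurements. The rule set before the data were examined required every sample to correlate best with its partner over all tested probes, and 5 of 6 dark and 4 of 6 light samples did. The 12 samples were therefore fitted as replicates. Over the 3193 probes above 0 in every sample, 6 of 6 dark and 6 of 6 light samples correlated best with their partner. The rule thus failed only with the 188 probes listed at 0 in 1 to 11 samples included. Without them the lowest correlation within dark pairs was 0.139 and the highest between pairs -0.090. In light these were 0.371 and 0.318. Whether partners are repeat measurements stays open. They were more alike than other samples of their group, so adjusted p values of the 12-sample fit are probably too small. No pair of samples had identical values. Results with the pairs as a random block (duplicateCorrelation) and with the pairs averaged are given beside the main count for this reason.

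Alternatives were no scaling, median centring, a filter on the dimmest 25% of probes, a pseudocount at the 10th percentile (0.223), the sample number as a block, the treatment of pairs, eBayes with trend and robust, a 2-fold minimum, arrayWeights, and leaving out each sample. Others were added after the data were seen: leaving out light 1 and 2 or numbers 1 and 2 of both groups, averaged pairs with a block or without light 1 and 2, probes with a 0 left out, a floor at the 5th percentile, the photosynthesis lists pooled, and shared probes added to lists. The fits were tested on simulated data with 3193 probes, 200 of them changed, over 20 runs. With pairs correlated at 0.692, as estimated from the data, the fit of 12 samples recovered 80.4% of changes of 1 log2 unit, the random block 62.6% and the averaged pairs 44.2%. The median numbers of false calls were 112.5, 8.5 and 5.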

Results

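Transcript levels were measured on 3439 array probes in 6 samples of bromoxynil-treated plants kept in darkness for 12 h and in 6 samples of treated plants that had light for 30 min after such a dark period. The labels name 1 comparison, light against dark in the presence of the herbicide. It asks which transcripts differ shortly after the return of light while bromoxynil is present. Without herbicide-free plants, the values describe light and dark under bromoxynil, and effects of the herbicide itself were not analysed here.

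Most called probes were higher in light. AT4G35660 rose 3.99-fold (log2 change 1.995 ± 0.18, limma adjusted p 1.39e-04), from a normalised log2 intensity of 0.99 ± 0.43 in the dark to 2.98 ± 0.14 in light (SD, n = 6 each). AT4G18180, a member of the pectin lyase-like family, rose 2.78-fold (1.47 ± 0.17, limma adjusted p 9.14e-04). CML30, a calmodulin-like protein of the calcium-binding EF-hand family, rose 1.64-fold (0.71 ± 0.10, limma adjusted p 0.00276). AGL103, a MADS-box protein of the AGAMOUS-like family, was 1.55-fold lower in light (-0.63 ± 0.09, limma adjusted p 0.00302). These were the 4 single-gene probes that also passed with sample pairs as a random block, at adjusted p values of 8.75e-04, 0.0382, 0.0419 and 0.0419. None of the 4 passed with pairs averaged, where adjusted p ran from 0.161 to 0.609. Without scaling, 0 of the 13 single-gene probes past the threshold were called, and AT4G35660 came nearest (adjusted p 0.0534). There AGL103 had a log2 change of 0.18, so its direction turned, but this lay below the median of 0.78 over all probes. Light 1 and 2, with deposited medians of 3.88 and 3.90 against 0.559 to 0.654 in the other samples, raise unscaled light means. After scaling, AGL103 changed by -0.77 in numbers 1 and 2, -0.60 in numbers 3 and 4 and -0.52 in numbers 5 and 6.

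AT5G64150 fell 2.41-fold (-1.27 ± 0.23, limma adjusted p 0.0164), but its adjusted p was 0.0686 with the sample number as a block, 0.0569 with the random block and 0.0520 without light 1 and 2. The change in AT5G64150 was -2.28 in numbers 1 and 2, -0.72 in numbers 3 and 4 and -0.82 in numbers 5 and 6. AT3G04210, a TIR-NBS protein of the disease resistance class, rose 2.39-fold (1.26 ± 0.20, limma adjusted p 0.00627). Its change was 1.77 in numbers 1 and 2, 0.89 in numbers 3 and 4 and 1.12 in numbers 5 and 6. AT3G54930, a regulatory subunit of protein phosphatase 2A, rose 1.56-fold (0.64 ± 0.09, limma adjusted p 0.00385). AT3G04210 and AT3G54930 missed the threshold with the random block, at adjusted p values of 0.0556 and 0.198. The other 6 single-gene probes past the threshold changed less. AT3G50130, AT2G39100, AT3G18870, AT5G11550 and AT2G44760 were higher in light, with log2 changes of 0.65, 0.51, 0.43, 0.37 and 0.34. AT1G03810 was lower, at -0.31. Its change was 0.54 without scaling, against the median of 0.78, and median centring ended its call (adjusted p 0.138). The limma adjusted p values of these 6 ran from 0.0217 to 0.0432. With the sample number as a block, AT3G18870 and AT2G44760 no longer passed (adjusted p 0.0905 and 0.0655). When each sample was left out in turn, AT5G11550 passed in 11 of 12 fits and failed without dark 3 (adjusted p 0.0521), and AT2G39100, AT3G50130, AT2G44760, AT3G18870 and AT1G03810 passed in 4, 3, 3, 2 and 2 of the 12. CML30, AT3G04210, AT3G54930 and these 6 genes lay outside the 10 largest changes in their direction and were chosen after their values were seen. Every gene named in these paragraphs as risen or lower moved in its direction in 6 of 6 sample numbers, as did all 96 probes past the threshold. That is not separate support, since the rule for the largest changes required it and partners among the numbers are correlated.

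**Figure D1:**
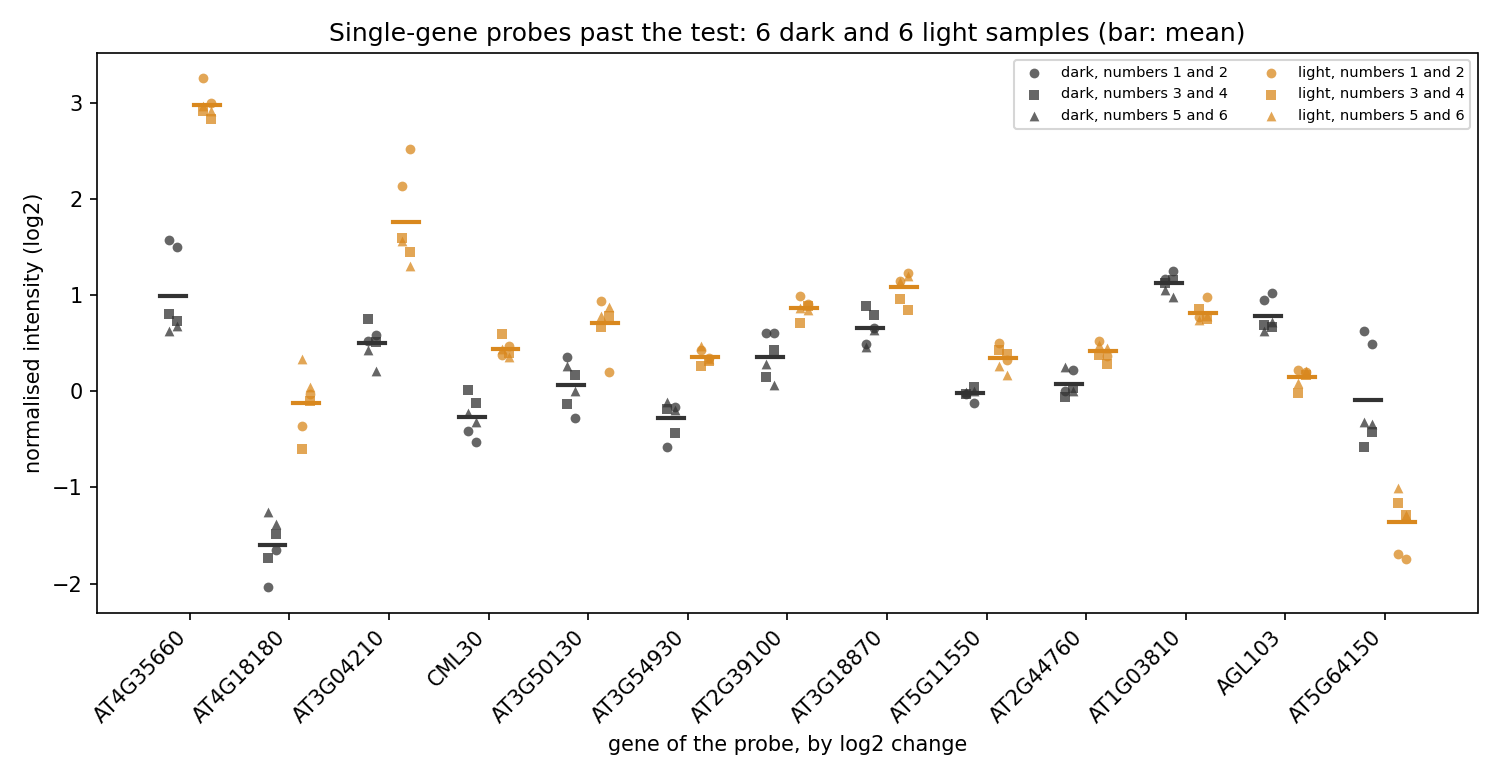
Normalised intensity (log2, vertical axis) of the 13 single-gene probes past the threshold, ordered by log2 change, with each dark sample in grey, each light sample in orange, bars at the group means and marker shapes for the sample pairs. AT4G35660 lies at a mean of 0.99 in the dark and 2.98 in light, and AT5G64150 at -0.09 and -1.36.

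Over all tested probes, 96 of 3381 (2.84%) passed the threshold, 70 higher and 26 lower in light. An unadjusted limma p under 0.05 was found for 639, where 169 are expected with no effect if the samples are independent. With sample pairs as a random block that number was 310. The median size of the called changes was 0.62 on the log2 scale, or 1.54-fold, and the range was -1.65 to 2.71. A change of 2-fold or more was reached by 14 probes that rose and 2 that fell. All 96 moved the same way in all 6 sample numbers, and none was listed at 0 in any sample. Of the 96, 13 had 1 annotated gene, 18 had several and 65 had none. Probe 750, which has no annotated gene, had the largest rise at 6.56-fold (2.71 ± 0.37), and probe 4201 rose by 2.22 ± 0.39. Probe 2890 fell by 1.65 ± 0.38 and probe 3513 by 0.91 ± 0.18. Both probe 4201 and probe 2890 are dim, and with the pseudocount their changes were 0.79 and -0.59, the second smaller than that of AT5G64150 (-0.91). Probe 2890 also missed the threshold with trend and robust (adjusted p 0.0646) and passed in 3 of 12 fits that each left out 1 sample. None of these 4 unnamed probes passed with the random block (adjusted p 0.214 to 0.263) or with pairs averaged (0.0669 to 0.804). Probe 3513 missed the threshold without dark 2 and without dark 3 (adjusted p 0.0519 and 0.0521).

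The count depended on how sample pairs were treated. With the pairs 1 and 2, 3 and 4, and 5 and 6 as a random block (consensus correlation 0.669), 16 probes passed, 15 higher and 1 lower, and all 16 were among the 96. With the pairs averaged, leaving 3 values a group, 1 probe passed, and it was not among the 96. In that fit 201 probes had an unadjusted p under 0.05, where 169 are expected with no effect. Leaving out dark 3, dark 4, light 5 or light 6 gave 46, 57, 60 and 58 probes, and values without scaling gave 2 higher and 0 lower.

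Light 1 and light 2 stood apart from the other 10 samples, and the first principal component, with 45.2% of the variance, separated them. Dark 1 and dark 2 stood apart on the second component (14.8%), with scores of 22.1 and 21.4 against -12.4 to 3.06 for the other 10 samples. The log2 changes had an SD across probes of 0.846 in numbers 1 and 2, against 0.325 in numbers 3 and 4 and 0.367 in numbers 5 and 6. Without light 1 and 2, 99 probes passed, 59 higher and 40 lower, and 63 of them were among the 96.

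**Figure D2:**
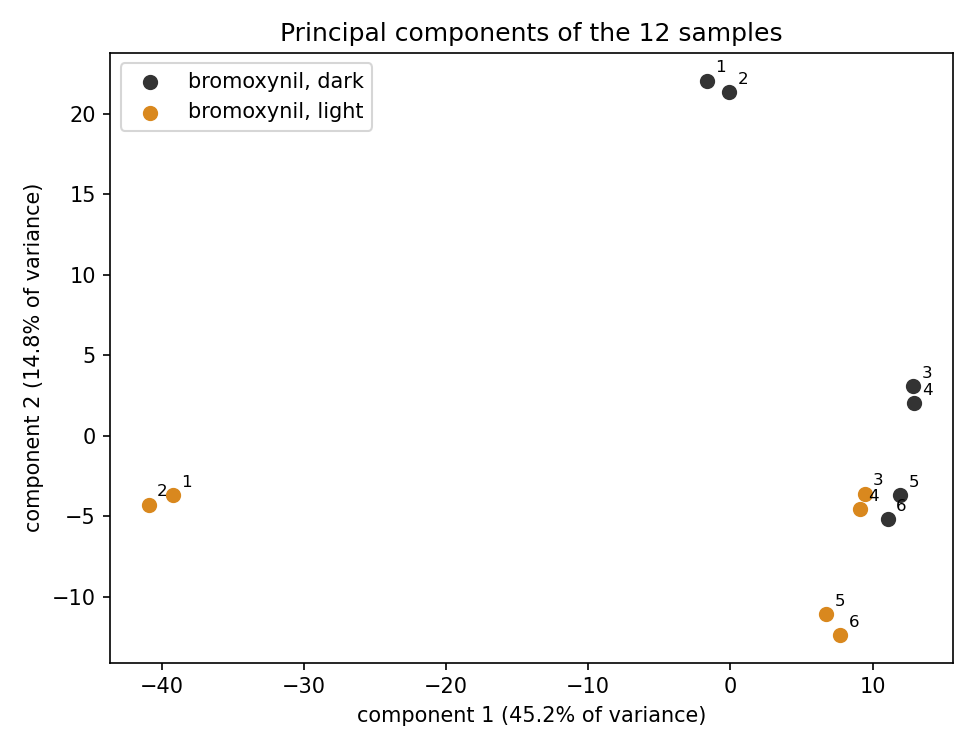
Scores of the 12 samples on the first component (horizontal axis, 45.2% of the variance) and the second (vertical axis, 14.8%), with dark samples in grey, light samples in orange and the sample number beside each point. Light 1 and 2 lie far to the left of the other 10 samples, dark 1 and 2 lie above all others, and samples 1 and 2, 3 and 4, and 5 and 6 of a group lie next to each other.

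None of the listed genes on single-gene probes passed the test over all probes. Of the 408 listed loci, 15 were on single-gene probes, in 9 of the 25 lists. With limma, 0 of the 15 passed, also with the sample number as a block, and 4 had an unadjusted p under 0.05. LHB1B2, a protein of the main light-harvesting antenna of photosystem II, was near the top of the intensity range in both groups, at the 99.1 percentile, and its log2 change was 0.02 (95% CI -0.22 to 0.25). That value joins 0.30 in numbers 1 and 2 with -0.06 in numbers 3 and 4 and -0.19 in numbers 5 and 6. PSBW, a small subunit of photosystem II, had a change of -0.91 ± 0.36 (limma adjusted p 0.200), made up of -2.10 in numbers 1 and 2, -0.17 in numbers 3 and 4 and -0.46 in numbers 5 and 6. PSBY, another small protein of that photosystem, had a change of 0.27 ± 0.10 (limma adjusted p 0.155). PSAN, a lumenal subunit of photosystem I, had a change of -0.42 ± 0.18 (limma adjusted p 0.247), which was -0.90 in numbers 1 and 2. Adjusted over the list alone, 2 of 2 photosystem II genes and 1 of 1 photosystem I gene passed, but 0 did with the random block (lowest adjusted p in the list 0.0508 and 0.0578) or with pairs averaged (0.130 and 0.180). Without scaling the lowest values were 0.137 and 0.415. PSAN also failed without light 1 and 2 (p 0.142) and with arrayWeights (p 0.287), and passed in 4 of 12 fits that each left out 1 sample. PSBW failed there without light 2, and with median centring or arrayWeights 1 of the 2 photosystem II genes and 0 of the photosystem I list passed. Without scaling the change of PSAN was 0.44, below the median of all probes. Adjustment over a list with 1 measured gene leaves its p as it was. Adjusted over all 15 listed genes in the main fit, 0 passed. There PSBY and PSBW had a limma adjusted p of 0.129 and PSAN of 0.165.

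In the Calvin cycle list, PRK, the phosphoribulokinase that regenerates the carbon dioxide acceptor, had a log2 change of 0.35 ± 0.13 (limma adjusted p 0.173), and SBPASE, a bisphosphatase of the same cycle, -0.14 ± 0.13. Adjusted over the list alone, 1 of these 2 genes, PRK, passed, but 0 did with the random block (adjusted p 0.282), with pairs averaged (0.149), with median centring (0.0796), with trend and robust (0.0548), without light 1 and 2 (0.0988) or without scaling (0.202), and PRK passed in 4 of 12 fits that each left out 1 sample. The 6 measured genes of the photosynthesis lists, pooled after the data were seen, had a median log2 change of -0.06 (camera p 0.811). With an estimated correlation the camera p was 0.812. Fry gave p 0.948 for a shift in 1 direction and p 0.0238 for changes in either direction. Both fry tests took the 12 samples as independent, so correlated partners may make these p-values too small. CHLM of chlorophyll synthesis had a change of 0.01 (95% CI -0.41 to 0.43), made up of 0.36 in numbers 1 and 2, -0.14 in numbers 3 and 4 and -0.20 in numbers 5 and 6. AT1G74470, the geranylgeranyl reductase that supplies the chlorophyll side chain, had 0.12, the plastid peroxiredoxin AT3G52960 had -0.19, and FATB, a plastid acyl carrier protein thioesterase, had 0.08. For these lists 0 members passed adjusted over the list alone, except with the sample number as a block, where AT3G52960, the only measured gene of the antioxidant list and lower in light in 6 of 6 sample numbers, had p 0.0143. With pairs averaged and a block its p was 0.163.

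Of the plastid ribosomal proteins 5 were measured and 0 passed, also adjusted over the list alone. Their median log2 change was 0.15 (camera p 0.297), with p 0.354 with an estimated correlation and p 0.449 with fry. The median was 0.095 without dark 3. AT1G64510 had the largest change among the 4 measured in every sample, 0.34 ± 0.21. Without dark 5 its change was 0.210, below the 0.216 of AT4G01310. AT5G65220 was listed at 0 in 11 of 12 samples, and only with it did the list reach the minimum of 5 measured members. Without dark 4, where AT5G65220 had no value, the camera p of the list was 0.179. A further 7 probes carry several genes that all stand on 1 list, and 0 of them passed. ELIP1, ELIP2, SIG5, LHCB1.3, RBCS1A, PSBS and NIT4 were on no single-gene probe, nor were the listed markers of non-green tissue or the listed cytosolic reference genes. PSBY, SBPASE and AT1G64510 were chosen after their values were seen.

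**Figure D3:**
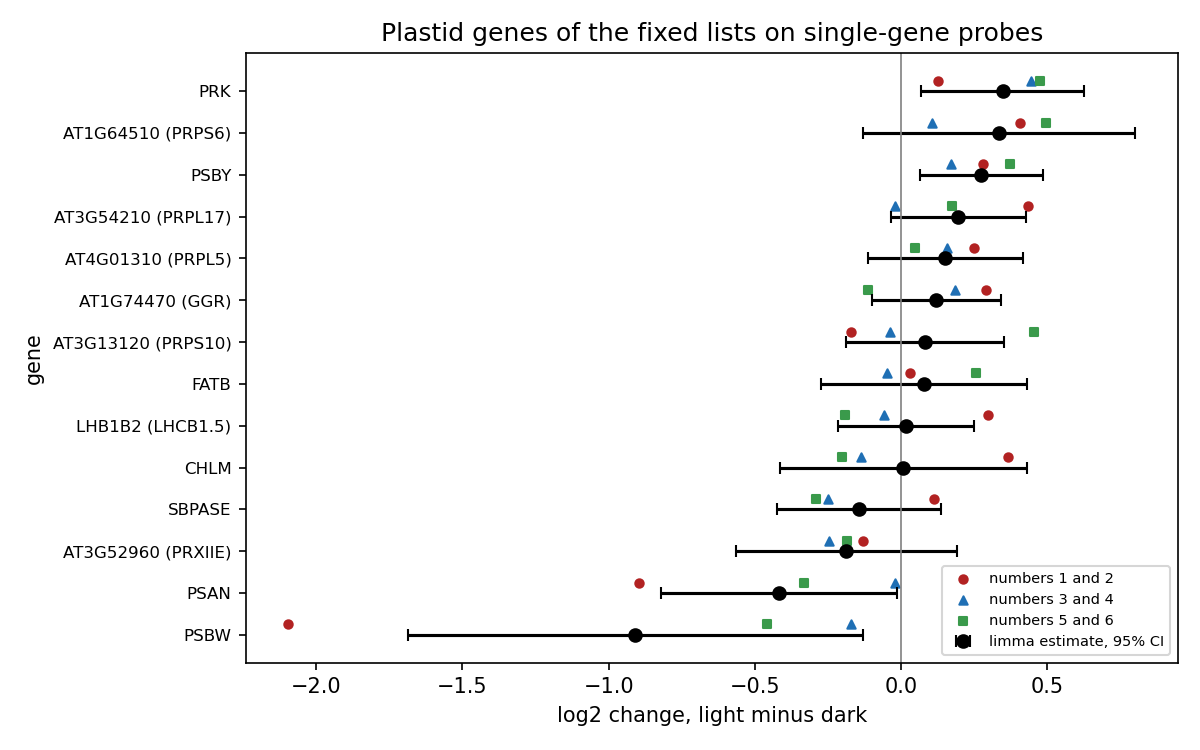
Log2 change (light minus dark, horizontal axis) of the 14 listed genes above 0 in every sample, with the limma estimate and 95% confidence interval in black and the mean change within each pair of sample numbers in colour. LHB1B2 lies at 0.02, and PSBW at -0.91 with numbers 1 and 2 at -2.10.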

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

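The tests of a scale distortion and of a shared filter batch were chosen after the results were seen. In 3 of 67 groups of 6 values the sample at an end lay far from the other 5, where chance gives about 1 in 20. Dark 1 had a normalised log2 intensity of -1.36 for probe 750, against a group median of -0.16. Dark 2 had -6.03 for probe 4201, against a group median of -3.87. Both low dark values add to the rises of these probes. Dark 4 had -7.26 for AT5G65220, which was listed at 0 in the other 11 samples.

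Light 1 and 2 differed from the other light samples. A change of scale that keeps the order of the spots is argued against, since their mean Spearman correlation with light 3 to 6 was 0.763 across probes and the lowest among light 3 to 6 was 0.943. A dark sample under a light label is argued against less firmly. Of 109 probes called from numbers 3 to 6 alone, 86 (78.9%, exact 95% CI 70.0% to 86.1%) had the same sign in numbers 1 and 2. Those probes share samples and are not independent trials, so the interval may be too narrow. A filter batch shared with dark 1 and 2 is argued against as the whole cause, because dark 1 and 2 correlated at 0.865 with dark 3 to 6 and light 1 and 2 at 0.732 with light 3 to 6. A partly shared batch remains open, as dark 1 and 2 also stood apart on the second principal component, as does a separate plant batch, labelling or background treatment of light 1 and 2, and no biological explanation was tested.

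The count fell from 96 to 1 when pairs were averaged. A candidate explanation is that repeat measurements were counted as replicates: simulated samples with the pair correlation of the data and no effect gave a median of 26 calls (5 to 46) in the fit of 12 and 0 with pairs averaged. With 200 changed probes, the fit of 12 gave a median of 112.5 false calls. The simulated samples had the same spread and no pairing of numbers across the groups, unlike the data. The simulation therefore cannot say how many of the 96 are such calls, and part or all may be. In the same simulated samples without an effect, the random block gave a median of 0 calls and at most 1. In the data it gave 16, all among the 96. The spread of light 1 and 2 stays open too: without them the counts were 99 and 2, but a fit of the 5 averages that remain has fewer degrees of freedom, so the low count does not argue against it. The share of the 96 that reflects light is open.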

How the results depend on the processing

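The settings that leave out light 1 and 2 or numbers 1 and 2, combine averaged pairs with another choice, leave out probes with a 0, set a 5th percentile floor, or pool the photosynthesis lists were chosen after the data were seen. Counts are probes called, then higher and lower in light, against 96, 70 and 26. Values without scaling gave 2, 2 and 0, with a median log2 change over all probes of 0.78. There AGL103 (0.18), AT1G03810 (0.54), PSAN (0.44), SBPASE (0.65) and AT3G52960 (0.68) turned sign, though all 5 lay below that median, and the ribosomal list, with a median of 0.94, turned to the lower side in camera (p 0.985). Averaged pairs gave 1, 0 and 1, with or without the replicate block, and 2, 1 and 1 without light 1 and 2. The random block gave 16, 15 and 1, and the 2-fold minimum 16, 14 and 2. arrayWeights gave 174, 102 and 72. Without numbers 1 and 2 the replicate block gave 47, 32 and 15, and without that block the counts were 109, 70 and 39. The lower count was 42 with the pseudocount, 40 without light 1 and 2 and 40 with the 5th percentile floor. Leaving out each sample gave 46 to 86, 40 to 61 and 6 to 25. The lower count was 6 without dark 3, 12 without dark 4, 14 without dark 2 or light 6, 16 without light 5 and 17 without light 2. The cause was not tested, with these exceptions. A fold minimum lowers a count by construction. Without scaling, light 1 and 2 kept medians of 3.88 and 3.90 against 0.559 to 0.654 in the other samples. That adds to the spread of the light group, so the low count there says little about the calls. Averaging pairs or leaving out a sample also leaves fewer degrees of freedom. Median centring gave 114, 93 and 21, the filter on the dimmest 25% of probes 110, and eBayes with trend and robust 101. The replicate block gave 116, 81 and 35, shared 66 with the 96 and ended the calls of AT5G64150, AT3G18870 and AT2G44760, and it brought AT3G52960 past the threshold adjusted over its list alone (p 0.0143). It changed no other call of a named gene or list. Among the gene lists, the ribosomal list kept a p above 0.05 in each setting run (camera p 0.135 to 0.985). The pooled photosynthesis lists did so with camera and in fry's test for 1 direction, but not in fry's test for either direction (p 0.0238). That fry test took the 12 samples as independent. Of 474 values of called named probes under alternatives, 314 kept call and direction, 158 lost the call and 2 turned sign. Of 413 values of named probes not called, 386 kept direction, 27 turned sign and 0 gained a call. Besides those without scaling, the changes that turned were small. LHB1B2 had -0.23 with median centring, -0.079 with arrayWeights, -0.12 without light 1 and 2 (pairs averaged or not) and -0.12 without numbers 1 and 2 (block or not). CHLM had -0.16 with arrayWeights, -0.21 without light 1 and 2 and -0.17 without numbers 1 and 2, in the same variants. FATB had -0.086 with median centring and -0.024 without light 1 and 2 (pairs averaged or not), and AT3G13120 -0.012 with median centring. Leaving out each sample gave -0.039 to 0.061 for LHB1B2 and -0.090 to 0.12 for CHLM. AT5G65220 had no value without dark 4 or with the 5th percentile floor, where all its samples were at the floor. Scaling on cytosolic reference genes was not run, since none was on a single-gene probe. The ribosomal list was not tested without the dimmest 25% of probes, where 2 members were left. It has 0 shared probes, so adding those moved nothing. Signal over background is unknown and limits dim probes such as 4201.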

Other observations

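The splits that keep pairs together were chosen after the results were seen. Of the 8 single-gene probes among the 40 brightest, 6 had their largest change in numbers 1 and 2, of which 5 were lower in light there and 1, LHB1B2, higher. Over all 3193 probes above 0 in every sample the share was 61.8%. CCL and AT3G13150 were the 2 others. AT3G09850 had a log2 change of -2.15 there and 0.10 in both other pairs, and AT2G27290 had -2.98 against -0.06 and 0.00. NdhS, a subunit of the plastid NDH complex, had -1.55 against -0.21 and -0.03. None of the 3 passed the test over all samples (limma adjusted p 0.385, 0.344 and 0.315), and they were chosen after their values were seen. In light 1 and 2 the brightest spot as deposited was below 100, its value in the other samples, although the medians were higher. Quantile normalisation evens out a change of scale that keeps the order of the spots. Whether another limit at the top of the scale lowered bright probes there, PSBW among them, was not tested. These falls may therefore not be changes in transcript level.

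Across 3193 probes, which are not independent replicates, the log2 changes of numbers 3 and 4 and of numbers 5 and 6, which share no sample, correlated at 0.450. The changes of numbers 1 and 2 correlated at 0.270 with each of the other pairs. Their covariances with numbers 3 and 4 and with numbers 5 and 6 were 0.0743 and 0.0837. That between numbers 3 and 4 and numbers 5 and 6 was 0.0536. The lower correlations thus go with the larger SD in numbers 1 and 2 (0.846 against 0.325 and 0.367), not with a smaller covariance.

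Of 100 drawn splits of the 12 samples, 1, the real split with 96 calls, gave as many, and the highest other gave 1. Of the 32 splits that part every sample number, 1 gave as many and the highest other gave 1. These splits exclude chance only if the 12 samples are independent, since most of them part the correlated partners. The 10 splits that keep partners together are too few for a share under 0.05: 1, the real split with 96, gave as many, and the highest others gave 33 and 14. The split with 33 set dark 1 to 4 and light 1 and 2 against the rest. With averaged pairs the 10 splits are too few as well: the real split gave 1, the highest other 1, and 3 splits gave as many.

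The probe called with averaged pairs, probe 2399, was lower in light (limma adjusted p 0.00490 there, 0.0702 over the 12 samples and 0.644 with the random block). It was listed at 0 in 2 samples, so the size of its change rests on the value set for 0 and is not given. Among annotated probes, 58.1% of the called (18 of 31) and 55.9% of the others (840 of 1504) carry several genes (Fisher's exact test, two-sided p 0.857).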
